A study of Mus musculus with 8 samples.

How the data were processed

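Livers of 8 mice of the C57BL/6N strain were taken at 27 days of age, and total RNA of each was hybridised to 1 Affymetrix GeneChip whole-transcript array, per the labels. Knockout mice carried an albumin-driven Cre, which is active in hepatocytes, and floxed alleles of Sco1, a mitochondrial copper chaperone needed for the assembly of cytochrome c oxidase (complex IV). Groups were taken from the titles, 4 knockout and 4 wild-type mice. The genotype labels divided the wild-type group further: mice 1 and 3 carried Cre with 1 floxed and 1 wild-type allele, and mice 2 and 4 had no Cre and floxed alleles, whereas the titles and the series text called all 4 floxed without Cre. The labels gave no sex, litter, collection time, slide or scan date, so none of these could be tested as a batch.

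The deposited values were RMA expression values for 39137 probe sets, made by the authors with the R package oligo version 1.24 per the submitters' processing notes. RMA corrects the background, normalizes the arrays to each other by quantiles and summarises the probes of a set, which holds the distribution of values nearly equal across arrays and pulls large differences toward 0. That the deposited values are on a log2 scale was inferred from the RMA method and from their range of 1.28 to 13.88, since no label states it. The chip definition and the genome build were not given in the sources used here. Probe sets were named through the array's platform annotation: 23521 had 1 gene symbol, 1814 had several and 13802 had none. By gene number, 23328 of the named probe sets were found in a reference gene table of the assembly GRCm38.p6, which changed no symbol. Only probe sets with 1 symbol were tested, and the probe set of the highest mean over all arrays stood for each of the 1082 genes with more than 1, which left 22180 genes.

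Differences were computed as knockout minus wild-type on the deposited log2 values with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided, group as the single term). P-values were adjusted by Benjamini-Hochberg over the 22180 genes, with a threshold of 0.05. Errors of differences are limma standard errors, and errors of group means are SDs over 4 mice. A second limma fit with 3 groups compared the knockout with each class of control and both control classes with each other. Sco1 also had an exact permutation test over the 70 assignments of 4 arrays out of 8, whose smallest p is 0.0286.

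Gene lists, 31 of pathways and 13 of cell types or zones, were written before the data were examined, as were the comparisons, the rule for named genes and all alternatives apart from 3 that are named as later choices. Of 982 listed members 882 were measured. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Separately, fry tested whether the genes of a list moved, on balance, one way, without comparing them with other genes. A further exact permutation test of each list's mean level relative to all genes was added after the camera results were seen. Transcripts of the mitochondrial genome were matched to the lists through a table of alternative names written after the files were seen. The genes named in the text are Sco1, the 15 largest rises and 15 largest falls past the threshold with non-overlapping groups, leaving out predicted, RIKEN, small RNA, receptor family and immunoglobulin symbols, up to 4 members of smallest adjusted p from each list, and any member of the copper and complex IV lists. Genes outside that rule are named as chosen later.

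On simulated data of the same size, with 200 changed genes in each of 10 trials, the limma step recovered 57.8% of changes of 0.5 log2 units, 93.7% of changes of 1 and 99.5% of changes of 2, and 5% of its calls were false. Simulated genes varied independently and normally, without correlation between genes or outlying arrays. These rates therefore need not hold for the real arrays. The alternatives were a trended robust variance, renewed quantile normalization, centring of arrays, 2 filters on dim genes, the mean of a gene's probe sets, all probe sets tested, mouse number as a block, array weights, a minimum fold of 1.2 in the test, the Y-linked level as a covariate, 3 treatments of the control classes, and each array left out in turn. Precision is limited by the number of arrays. Files were read with Python version 3.11.15 and pandas version 2.3.3, and plots were drawn with matplotlib version 3.10.9.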

Results

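Gene expression was measured in liver RNA of 4 mice with a hepatocyte knockout of Sco1 and 4 wild-type control mice at 27 days of age, with 1 array per mouse. Array medians lay between 5.79 and 5.89 on the log2 scale. Arrays correlated across genes at 0.9915 to 0.9946 within the knockout group and at 0.9939 to 0.9954 within the wild-type group. The first principal component held 28.7% of the variance and separated the groups, with knockout arrays at 9.2 to 21.8 and wild-type arrays at -18.1 to -6.8.

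Sco1 itself (probe set 17250948) was measured at 7.59 ± 0.10 log2 units in the knockout livers and at 8.00 ± 0.15 in the wild-type livers (SD, n = 4 each). Every knockout array lay below every wild-type array, the highest knockout value being 7.72 and the lowest wild-type value 7.84. The difference of -0.41 ± 0.09 (SE) put the knockout mean at 75.4% of the wild-type mean. It missed the threshold over all genes (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0633; 0.036 to 0.313 over 23 alternative settings, of which 5 passed), while the exact permutation test of this single gene gave the smallest p that 4 arrays against 4 allow, 0.0286. Control mice with 1 floxed allele and Cre averaged 8.01 and Cre-free controls 7.99. Which exons the probes of this set cover was not known, so the size of the difference does not measure how much of the deleted part remained, and non-hepatocytes, in which the albumin promoter is silent, also contribute Sco1 RNA.

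The comparison of knockout with wild-type livers asks what the loss of Sco1 in hepatocytes changes in the liver transcriptome. Nupr1, a stress-induced chromatin protein, had the largest rise, from 6.82 ± 0.13 to 9.22 ± 0.60 log2 units (SD, n = 4 each), a difference of 2.41 ± 0.24 (SE) or 5.30-fold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00226). Sult1c2, a cytosolic sulfotransferase, rose by 2.19 ± 0.20, the tubulin gene Tuba8 by 1.75 ± 0.15 and the desmosomal cadherin gene Dsg1c by 1.70 ± 0.22. The largest fall was that of the serpin pseudogene Serpina4-ps1, which fell by 2.73 ± 0.41, a 6.63-fold difference. Ugt2b37, a glucuronosyltransferase, fell by 1.25 ± 0.24, the major urinary protein gene Mup21 fell by 1.23 ± 0.16, and Cyp26a1, which clears retinoic acid, fell by 1.199 ± 0.191. With the least favourable array left out, adjusted p rose to 0.099 for Ugt2b37 and 0.0543 for Cyp26a1, which ended the calls. They were kept with 3 and 5 of the 8 arrays left out in turn.

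Rragd, a GTPase that recruits mTORC1 to the lysosome, rose by 1.39 ± 0.18, the late endosomal tetraspanin gene Cd63 by 1.37 ± 0.14, Gpnmb, a glycoprotein gene that macrophages also express, by 1.23 ± 0.12, and Cln6 by 1.19 ± 0.14 (SE, n = 4 each). Annexin Anxa8 rose by 1.31 ± 0.14, the phospho-lyase gene Etnppl by 0.92 ± 0.07, Adam11 by 0.82 ± 0.13 and Mrgpre by 0.81 ± 0.12. Fabp2, an intracellular fatty acid binding protein gene, fell by 1.10 ± 0.12, the potassium channel gene Kcnt2 fell by 1.10 ± 0.16, Cyp2d40 fell by 1.06 ± 0.15, the adipokine gene Serpina12 fell by 1.01 ± 0.17, the histone gene H2bc9 fell by 0.98 ± 0.18 and Tdrkh fell by 0.96 ± 0.10. The adjusted p of these genes lay between 0.000946 and 0.033. With the least favourable array left out it was 0.0579 for Adam11, 0.0717 for Serpina12 and 0.0969 for H2bc9. These calls were kept with 6, 3 and 2 of the 8 arrays left out in turn. Mup21, Ugt2b37, Cyp2d40, Serpina4-ps1 and H2bc9 belong to families of near-identical copies, and their probe sets may read relatives as well.

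In all, 96 genes rose and 159 fell at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 12 and 11 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1910 higher and 1787 lower genes. Groups did not overlap for any of the 255 changed genes, nor for 10.7% of all genes, against 2.86% by chance. Higher genes made up 37.6% of the calls, and 21.4% (81 higher and 298 lower) when each array was centred on its median. Higher and lower counts were 37 and 76 without knockout mouse 1, 65 and 101 without knockout mouse 2, 33 and 85 without knockout mouse 3, 56 and 119 without knockout mouse 4, 53 and 88 without wild-type mouse 1, 31 and 60 without wild-type mouse 2, 29 and 84 without wild-type mouse 3, and 29 and 69 without wild-type mouse 4. Without both mouse 1 arrays, which stood apart in the clock gene Dbp, the counts were 28 and 37, and with the level of Y-linked genes, low in knockout mouse 4, as a covariate they were 45 and 106. The count of falls of at least 2-fold was 7 without knockout mouse 1 and 7 without wild-type mouse 2. Of the 53 named genes past the threshold, 26 passed with any 1 array left out, among them Nupr1, Sult1c2, Tuba8, Dsg1c, Rragd, Cd63, Gpnmb, Cln6, Anxa8, Etnppl, Irf7, Usp18, Serpina4-ps1, Mup21, Fabp2, Kcnt2, Tdrkh, Ido2, Cdc20 and Nusap1, and 27 lost the call without at least 1 array.

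**Figure D1:**
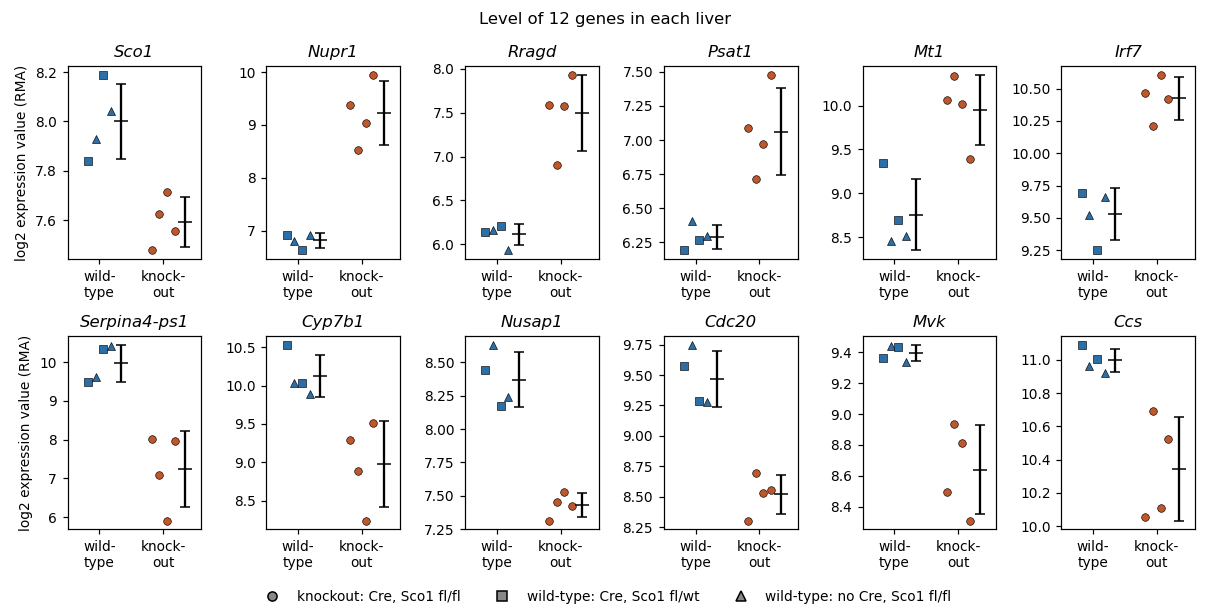
Log2 expression value (vertical axes, scaled per gene) of 12 genes in each of the 4 wild-type and 4 knockout livers, with the mean and SD of each group beside the points; marker shapes give the genotype class. Knockout and wild-type values do not overlap in any panel, and Sco1, with a difference of -0.41, is the one gene shown that missed the threshold.

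Genes of the cell cycle were lower in the knockout livers. Of 33 measured members 19 fell, none rose and 14 did not pass, and 26 were lower when adjusted over the list alone, with a list median of -0.64 log2 units. Cdc20, an activator of the anaphase-promoting complex, fell by 0.95 ± 0.12, the spindle protein gene Nusap1 fell by 0.94 ± 0.11, the spindle motor gene Kif11 fell by 0.89 and the midzone protein gene Prc1 fell by 0.70 (SE, n = 4 each). Hmmr and Depdc1a, mitotic genes outside the list, fell by 1.07 ± 0.11 and 1.14 ± 0.17. The list passed camera at adjusted p = 1.8e-30 and did not pass at adjusted p = 0.275 with an estimated correlation. Its exact permutation p was 0.0286, the smallest possible.

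Cholesterol synthesis genes were lower as well. All 19 measured members had negative differences, 4 of them fell past the threshold, 15 did not pass, and 16 were lower when adjusted over the list alone, with a median of -0.43. Mevalonate kinase, Mvk, fell by 0.76 ± 0.13, Cyp51 fell by 0.66 ± 0.12, Msmo1 fell by 0.54 ± 0.10 and Nsdhl fell by 0.48 ± 0.10 (SE, n = 4 each). The list passed camera at adjusted p = 1.19e-15 but not at adjusted p = 0.275 with an estimated correlation, and its exact permutation p was 0.0286. Each of these 4 single-gene calls was lost without any 1 of wild-type mice 2, 3 and 4, and with the least favourable array left out the adjusted p was 0.0671 for Mvk, 0.0876 for Msmo1, 0.103 for Cyp51 and 0.125 for Nsdhl. With the 8 arrays left out in turn, the Mvk call was kept 4 times and each of the others 1 time.

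Genes of the integrated stress response, induced through ATF4, were higher. Of 29 measured members 4 rose, none fell and 25 did not pass, and 12 were higher when adjusted over the list alone, with a median of 0.17. Beside Nupr1, the members that rose make amino acids: Psat1 rose by 0.77 ± 0.14 and Phgdh by 0.41 ± 0.09, both of serine synthesis, and asparagine synthetase, Asns, rose by 0.67 ± 0.13 (SE, n = 4 each). The camera test gave adjusted p = 3.02e-06, and adjusted p = 0.275 with an estimated correlation, and the exact permutation p was 0.0286. With the least favourable array left out the adjusted p was 0.0845 for Psat1, 0.112 for Asns and 0.133 for Phgdh. With the 8 arrays left out in turn, the Psat1 call was kept 2 times, the Phgdh call 1 time and the Asns call 0 times (lowest adjusted p 0.0578). Endoplasmic reticulum chaperones were lower in camera (adjusted p = 1.49e-05, and adjusted p = 0.453 with an estimated correlation), with all 18 measured members negative, none past the threshold over all genes, 4 lower when adjusted over the list alone, and an exact permutation p of 0.114. Pdia6 stood at -0.46 ± 0.12 and Sdf2l1 at -0.56 ± 0.16, with adjusted p of 0.0951 and 0.125.

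Copper handling genes moved both ways. Of 20 measured members metallothionein Mt1 rose by 1.196 ± 0.219 (adjusted p = 0.0312) and Ccs, the copper chaperone of superoxide dismutase, fell by 0.65 ± 0.13 (adjusted p = 0.0483), and 18 did not pass (SE, n = 4 each, limma with Benjamini-Hochberg adjustment). Adjusted over the list alone, 2 were higher and 2 lower. Mt2 differed by 0.98 ± 0.22 (adjusted p = 0.0591) and the metalloreductase Steap4 by -0.41 ± 0.09 (adjusted p = 0.0503). The importer Slc31a1 differed by -0.08 ± 0.07, the exporter Atp7b by -0.12 ± 0.07 and Sod1 by -0.11 ± 0.07, with adjusted p of 0.392 or more. The list median was -0.10, its mean 0.01 and its camera direction lower, at adjusted p = 0.172 (adjusted p = 0.425 with an estimated correlation). The Mt1 call was lost without any 1 of knockout mice 1, 2 and 3 or wild-type mice 2, 3 and 4, and the Ccs call without any 1 array other than knockout mouse 2, with adjusted p of up to 0.0913 and 0.122. Without knockout mouse 4, Mt2 passed at adjusted p = 0.0122. Steap4 missed the threshold with any 1 array left out (lowest adjusted p 0.0533), but its lowest adjusted p over all alternative settings was 0.0257.

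No gene of complex IV passed in the main comparison. Among 21 measured assembly factors 1 was lower when adjusted over the list alone, and Surf1 stood at -0.41 ± 0.09 (adjusted p = 0.0532). Among 13 nuclear subunits 1 was higher when adjusted over the list alone, and Cox7a1, the heart and muscle isoform, stood at 0.73 ± 0.16 (adjusted p = 0.055; SE, n = 4 each). Without knockout mouse 2 both passed, Cox7a1 at adjusted p = 0.021 and Surf1 at 0.0471. The lowest adjusted p of Surf1 over all alternative settings was 0.0295, so it also passed under an alternative other than leaving out 1 array. Camera gave adjusted p = 0.26 for the assembly factors (adjusted p = 0.494 with an estimated correlation) and 0.0816 for the subunits (adjusted p = 0.425 with an estimated correlation), while fry, which sets a list against no change and not against other genes, placed the subunits higher at adjusted p = 0.0303. Relative to all genes the subunits lay higher by 0.112 on average, with an exact permutation p of 0.0286 (0.0899 after Benjamini-Hochberg adjustment). For the assembly factors the exact permutation p was 0.114. None of the 10 measured transcripts of the mitochondrial genome passed, COX1 standing at 13.66 in knockout and 13.61 in wild-type livers, close to the highest value in the table, 13.88, where the array has little room to show a rise. Nor did any of 31 nuclear subunits of complex I, 13 of complexes II and III or 15 of ATP synthase, with list medians of 0.01, 0.11 and 0.02, the mean and the camera direction of complex I lying on the negative side. The exact permutation p of these lists were 0.6, 0.0286 and 0.914. Mitochondrial ribosome genes were lower in camera (65 measured, median -0.09, adjusted p = 8.82e-06, and adjusted p = 0.425 with an estimated correlation), with 1 member, Mrps25, that fell by 0.39 ± 0.08, 64 that did not pass, 3 lower when adjusted over the list alone, and an exact permutation p of 0.0286. The Mrps25 call was lost without any 1 array other than knockout mouse 4 (adjusted p up to 0.129).

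Inflammation and interferon genes were higher. Of 29 measured members 4 rose, none fell and 25 did not pass, and 8 were higher when adjusted over the list alone, with a median of 0.15. All 4 are interferon-induced genes: Irf7 rose by 0.89 ± 0.12, Gbp3 by 0.56 ± 0.12, Usp18 by 0.55 ± 0.08 and Oasl2 by 0.42 ± 0.08 (SE, n = 4 each). The list passed camera at adjusted p = 0.000728 but not at adjusted p = 0.425 with an estimated correlation, with an exact permutation p of 0.0286. With the least favourable array left out the adjusted p was 0.129 for Gbp3 and 0.118 for Oasl2. Each of these calls was kept with 1 of the 8 arrays left out in turn. Of the immune cell marker lists, those of macrophages and lymphocytes were higher in camera. None of 13 neutrophil markers passed, and nor did their list (adjusted p = 0.495, and adjusted p = 0.732 with an estimated correlation). Of 20 Kupffer cell and macrophage markers 1, Gpnmb, rose, 19 did not pass and 2 were higher when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00102, and adjusted p = 0.494 with an estimated correlation; exact permutation p = 0.114), and Cd68 stood at 0.36 ± 0.09. None of 18 lymphocyte markers passed, none when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00818, and adjusted p = 0.425 with an estimated correlation; exact permutation p = 0.0286), Cd3e standing at 0.37 ± 0.12. Without knockout mouse 4 both marker lists missed the camera threshold, at adjusted p = 0.0575 and 0.136. Of 11 skeletal and heart muscle markers none passed and 1 was higher when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.031, and adjusted p = 0.425 with an estimated correlation; exact permutation p = 0.0286), Myh2 standing at 0.38 ± 0.10. That call was lost without knockout mouse 2 (adjusted p = 0.122), knockout mouse 3 (0.0699), wild-type mouse 2 (0.0762) or wild-type mouse 4 (0.0504). Myh2 was dim, with means of 5.95 in knockout and 5.56 in wild-type livers, near the array medians. Dim genes in general lay slightly higher in the knockout: the median difference was 0.0268 over all genes and -0.022 among the brighter 11090 genes.

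Some lists of hepatocyte metabolism were lower in camera and others did not pass. Of 21 measured bile acid genes 2 fell, the bile acid conjugating enzyme gene Baat by 0.47 ± 0.08 and Cyp7b1, an oxysterol hydroxylase of the acidic pathway, by 1.14 ± 0.24 (SE, n = 4 each), 19 did not pass and 2 were lower when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00262, and adjusted p = 0.425 with an estimated correlation; exact permutation p = 0.0286). None of 34 drug-metabolising P450 genes passed, none when adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00262, and adjusted p = 0.425 with an estimated correlation; exact permutation p = 0.114). Cyp2c40 stood at -0.44 ± 0.10, Cyp2a5 at -0.71 ± 0.23 and Cyp2a4 at -0.91 ± 0.30, and Cyp2b10 the other way at 0.80 ± 0.26. Their adjusted p lay at 0.0713 to 0.169. Cyp2a4 and Cyp2a5 are near-identical copies whose probe sets may read each other. Cyp2a5 passed without wild-type mouse 2 (adjusted p = 0.0302) and Cyp2a4 without knockout mouse 3 (adjusted p = 0.0357). In the list of fatty acid oxidation and PPARA targets, 31 measured, the single call was the omega-hydroxylase gene Cyp4a14, which rose by 0.45 ± 0.09 against the direction of the list, 30 did not pass, and 2 were higher and 1 lower when adjusted over the list alone. Its median was -0.10 (camera adjusted p = 0.0058, and adjusted p = 0.425 with an estimated correlation; exact permutation p = 0.114), and Acot2 stood at 0.38 ± 0.10. None of 31 genes of hepatocyte secreted proteins and regulators passed, none when adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.0218, and adjusted p = 0.275 with an estimated correlation; exact permutation p = 0.0286), and Mbl2 stood at -0.23 ± 0.08. Without wild-type mouse 1 the bile acid list missed the threshold at adjusted p = 0.0534 and the fatty acid oxidation list at 0.0704, and with the least favourable array left out the single-gene adjusted p was 0.0565 for Baat, 0.116 for Cyp7b1 and 0.132 for Cyp4a14. These calls were kept with 5, 1 and 1 of the 8 arrays left out in turn. Camera did not pass the lists of the urea cycle and amino acid catabolism (adjusted p = 0.299), fatty acid synthesis (0.491), gluconeogenesis and glycogen (0.529), glycolysis and hypoxia (0.539) and lipid droplets and lipoproteins (0.94). Nor did it pass the tricarboxylic acid cycle, whose direction was higher (0.0816). With an estimated correlation the adjusted p of these lists lay at 0.494 to 0.938.

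Single members changed in lists that did not pass as a whole. Idh2 of the tricarboxylic acid cycle rose by 0.38 ± 0.07, the fatty acid uptake gene Cd36 by 0.53 ± 0.11, the lipid droplet gene Plin4 by 0.58 ± 0.12, Ugdh by 0.37 ± 0.08 and the dicarboxylate transporter gene Slc13a3 by 0.55 ± 0.10 (SE, n = 4 each). The aldehyde oxidase gene Aox1 fell by 0.57 ± 0.11, the tryptophan catabolic gene Ido2 fell by 0.68 ± 0.08 and the death receptor gene Fas fell by 0.41 ± 0.08. Of these Ido2 passed with any 1 array left out, and for the others the adjusted p reached 0.0762 (Slc13a3) to 0.131 (Fas). With the 8 arrays left out in turn, the Slc13a3 call was kept 2 times, the calls of Cd36, Plin4, Aox1 and Fas 1 time each, and those of Idh2 and Ugdh 0 times. Of the 44 lists 5 were higher and 8 lower in camera, and with an estimated correlation 0 passed. Fry called 2 higher, the integrated stress response and the complex IV subunits. It called 3 lower, the cell cycle, cholesterol synthesis and hepatocyte secreted proteins. The smallest exact permutation p was reached by 9 of the 13 lists called and by 14 of all 44, and none passed after Benjamini-Hochberg adjustment of those (smallest adjusted p = 0.0899). The count of lists called higher was 8 without knockout mouse 1 and 3 without knockout mouse 4.

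**Figure D2:**
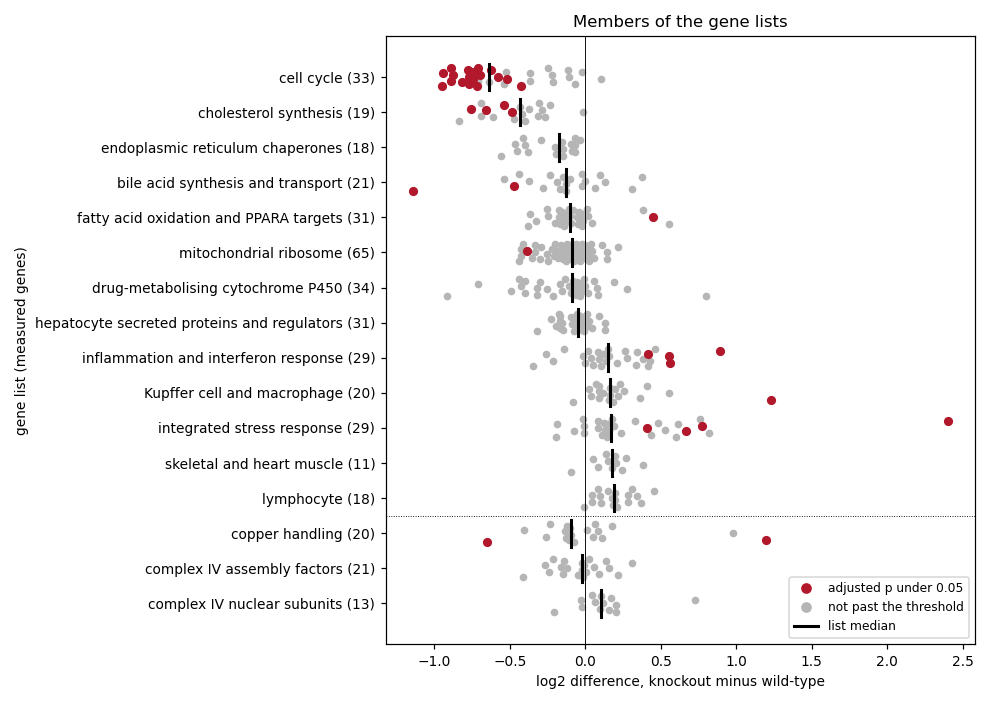
Log2 difference, knockout minus wild-type (horizontal axis), of each measured member of the 13 gene lists past the camera threshold and, under the dotted line, of 3 lists on copper and complex IV that did not pass. Red points are genes past the threshold over all genes, grey points are the others, and black bars are list medians; the cell cycle median lies at -0.64 and 19 of its 33 members are red.

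Control mice were of both genotype classes, so the knockout was also set against each class. Against the Cre-free floxed controls (n = 2) 15 genes rose and 32 fell, and against the Cre-carrying heterozygous controls (n = 2) 13 rose and 16 fell (limma with Benjamini-Hochberg adjustment), with 20 genes changed against both. All 255 genes of the main comparison had the same direction against either class. That was fixed in advance, since their knockout and wild-type values did not overlap, and is no separate evidence. Serpina4-ps1, the largest fall, differed by -2.77 from the Cre-free and by -2.69 from the heterozygous controls, and missed the threshold in both with adjusted p of 0.0875 and 0.12. Sco1 differed by -0.39 from the Cre-free and by -0.42 from the heterozygous controls. No gene differed between both control classes in limma or under any alternative of the fit (0 genes, 671 at an unadjusted p under 0.05 where chance gives 1109). With 2 mice in each class this does not show that the classes are alike. The counts against Cre-free and against heterozygous controls were 3 and 0 without knockout mouse 1, 11 and 12 without knockout mouse 2, 2 and 0 without knockout mouse 3, 18 and 7 without knockout mouse 4, 16 and 2 without wild-type mouse 1, 0 and 6 without wild-type mouse 2, 16 and 1 without wild-type mouse 3, and 6 and 6 without wild-type mouse 4, a lone control being assumed to vary like the other arrays.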

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

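The tests below were written down only after the results were seen, and this holds for the counts of other splits too. Levels of the genes named in the text, of sex-linked genes and of the clock genes Dbp and Per1 were examined in each group of 4 arrays, and 160 groups gave 14 arrays far from the other 3, where chance gives 8.

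Dbp, a clock output gene with a strong daily rhythm, stood at 9.66 in knockout mouse 1 and at 9.86 in wild-type mouse 1, far above the highest of the other 6 arrays, 7.33. Of 15 other clock genes, 14 lay in both mouse 1 arrays on the side that a shift of phase toward high Dbp predicts, where 3.75 would by chance (exact binomial test that treats genes as independent, one-sided p = 4.28e-08), which is consistent with collection of both mice at another time of day. An array batch shared by these mice stays open, since the deviations of genes outside the clock also correlated between both arrays, at 0.254 across genes, and either explanation gives that. One such array lies in each group, and the Dbp difference does not follow genotype.

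Kdm5d stood at 7.37 and Uty at 7.23 in knockout mouse 4, where the other 7 arrays lay at 8.40 to 8.78 and 8.48 to 8.83, and Eif2s3y at 7.49. These Y-linked transcripts were 2.4 to 2.61-fold lower than in the other knockouts. RNA of a female animal in the sample may account for it, yet Xist lay -0.043 from the highest of the other arrays, near the floor, and no array of a known female shows whether its probe set reads Xist. Of 3 X-linked genes with Y-linked partners, Ddx3x stood at 10.55, above the other arrays (10.10 to 10.29), in the direction of a female, while Kdm6a (8.92) and Kdm5c (9.44) lay within them. Female-biased liver genes, chosen later, were not raised in this array. Cyp2b9 stood at 10.08, Cyp2b13 at 4.98 and Sult2a1 at 4.86, each within the other arrays and the last 2 near the floor. The case stays open, and no biological explanation was tested.

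Rragd, Cd63, Gpnmb and Cln6 rose by at least 2-fold. With 6 further genes they made 10 risers among 78 measured genes of a list, written afterwards, of the lysosome and its regulators. An even rise of all macrophages in the knockout livers is argued against as the whole cause for the 4. The 19 macrophage markers outside these genes had a median of 0.161, and 0.455 after adding 2 SD across markers (0.713 with Gpnmb among them), under the smallest rise of the 4 (1.19). This comparison cannot see a rise of a macrophage subset, which stays open, and Gpnmb is itself on the macrophage list. For the 6 genes an even rise of macrophages stays open too, since their rises began at 0.375 (median 0.451), within that spread, and the largest marker difference was 0.556. The whole lysosomal list had a median of 0.112. A raised lysosomal programme could extend to the 68 list genes that did not pass, of which 54 were positive (camera p = 0.000326), but p was 0.122 with an estimated correlation and the exact permutation p 0.0571, so it stays open.

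Single arrays that lay far from the other 3 of their group were these. Gpnmb stood at 5.25 in wild-type mouse 4. Kcnt2 stood at 6.36 in knockout mouse 4. Tdrkh stood at 6.42 in wild-type mouse 1. Prc1 stood at 8.57 in wild-type mouse 2. Gbp3 stood at 6.76 in wild-type mouse 3. Mbl2 stood at 10.38 in wild-type mouse 2. Cyp2a4, which did not pass, stood at 10.48 in knockout mouse 3 and at 9.76 in wild-type mouse 2. Cyp2b10, which did not pass, stood at 8.81 in knockout mouse 4. Krt23, a cholangiocyte marker that did not pass (-0.60 ± 0.15 over the groups), stood at 6.63 in wild-type mouse 1.

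Other splits of the 8 arrays into 4 and 4 were counted, 35 with the real one. For genes higher (96), lower (159), higher by at least 2-fold (12) and lower by at least 2-fold (11), 1 split, the real one, gave as many, and the highest count of the other splits was 1 in each case. That is the smallest share that 35 splits allow. The other splits mix the groups, so a group difference widens their spread and lowers their counts. The real grouping thus stood out, but chance is not excluded for these counts. For gene lists called by camera, 13 splits gave as many as the 5 higher lists and 3 gave as many as the 8 lower lists, the real split included, with up to 9 in another split, so chance is not excluded for either count of lists. Each other split was counted by the larger of its higher and lower counts, the real split by the direction named. This is strict on the real split.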

How the results depend on the processing

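Leaving out both mouse 1 arrays, leaving out knockout mouse 3 for the male-biased list, and taking the Dbp level as a covariate were chosen after the data were seen. No called gene or list named in the text turned direction under any setting tried. For the genes most settings could not have turned it. Their groups did not overlap, so leaving out arrays or controls keeps the sign. Filters on dim genes, a minimum fold and another variance estimate leave the difference itself unchanged. Under the gene-level settings that keep all 8 arrays, 15 to 53 of the 53 named genes past the threshold passed again; with 1 array left out, 26 to 39, without both mouse 1 arrays 25, with Cre-free controls alone 12 and with heterozygous controls alone 5. The cause of a change was not tested, except that leaving out arrays or genes, testing every probe set or asking for a minimum fold changes the number of arrays, tests or calls by construction. Sco1 passed under 5 of 23 settings, with adjusted p of 0.036 to 0.313. Other named genes that missed the threshold also gained calls, up to 6 of 18 when the brighter genes alone were tested. Among such genes, the lowest adjusted p over all settings was 0.015 for Pdia6, 0.0257 for Steap4, 0.0314 for Krt23 and 0.0424 for Cyp2c40.

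Counts that follow are genes higher and lower in knockout, unless named. A trended robust variance gave 159 and 300, with 76 genes against Cre-free and 54 against heterozygous controls, and Sco1 (-0.41) passed at 0.0464. Centring gave 298 lower genes and Sco1 (-0.44) at 0.0492. Leaving out genes with a mean under 5 gave 150 and 289, 48 against heterozygous controls, and Sco1 (-0.41) at 0.043. Testing the brighter 11090 genes alone gave 319 lower genes, 9 lists higher and 5 lower, and Sco1 (-0.41) at 0.036. Every probe set tested on its own gave 17 and 25, 5 lower by at least 2-fold. Array weights gave 245 lower genes, and 97 and 10 against the control classes. A minimum fold of 1.2 gave 11 and 10, 3 lower by at least 2-fold. The Y-linked covariate gave 45 higher genes, 20 and 7 against the control classes, and 3 lists higher. Separate control groups gave 58 higher genes. Cre-free controls alone gave 7 and 9, 6 and 6 by at least 2-fold, and 4 lists lower; heterozygous controls alone gave 4 and 2, 3 and 2 by at least 2-fold. Without both mouse 1 arrays there were 28 and 37, and 3 and 2 against the control classes. With the Dbp covariate there were 294 lower genes, 23 against Cre-free controls, and Sco1 (-0.41) at 0.0384. Renewed quantile normalization gave 8 lists higher; camera with an estimated correlation gave 0 and 0 lists, and fry 2 higher and 3 lower.

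Deviations of same-numbered mice correlated at 0.273, -0.0217, 0.0308 and -0.102 for mice 1 to 4. Pairs of unlike number lay at -0.148 to 0.116. The mouse 1 arrays thus deviated together, and mice 2 to 4 showed no pairing by number. With mouse number as a replicate block there were 68 higher and 142 lower genes, and 0 genes against Cre-free and 0 against heterozygous controls.

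With 1 array left out, counts ran from 29 to 65 genes higher and 60 to 119 lower, 10 to 13 higher and 7 to 13 lower by at least 2-fold, 0 to 18 against Cre-free and 0 to 12 against heterozygous controls, 3 to 8 lists higher and 6 to 9 lower, and Sco1 from -0.46 to -0.34. Genes near the floor of the array, and mitochondrial transcripts near its ceiling, limit what a difference can show. The median difference was 0.0268 over all genes and -0.022 among the brighter 11090 genes. Small list shifts, such as the median of -0.05 for hepatocyte secreted proteins, are hard to tell from such a shift with level.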

Other observations

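The male-biased list and its tests were chosen only after the largest falls were seen. Several of those falls belong to genes known for higher expression in male than in female mouse liver under growth hormone. The list used holds male-biased genes together with growth hormone pathway genes such as Ghr, Stat5b and Igf1. Of its 30 measured genes 5 fell past the threshold, Serpina4-ps1, Ugt2b37, Mup21, Serpina12 and Cyp7b1, none rose, and 25 did not pass, with a median of -0.30. Since these 5 falls prompted the list, its median and count are no independent evidence of a direction. Knockout mouse 3 stood apart on the list, at -1.02 from the wild-type mean against -0.237, -0.439 and -0.256 in knockout mice 1, 2 and 4, and without it the mean shift went from -0.488 to -0.311 and the calls of Serpina12 and Cyp7b1 were lost. With the 8 arrays left out in turn, these calls were kept 3 times and 1 time, so their loss was not particular to that mouse. In the same mouse Cyp2b13 and Sult2a1, female-biased genes chosen after their values were seen, stood at 8.87 and 8.88, where the highest of the other arrays were 6.73 and 6.30. Cyp2b9, another female-biased gene, stood less apart there, at 12.61 against up to 11.94 elsewhere. In knockout mice 1 and 4 it lay at 9.83 and 10.08, below every wild-type array (10.85 to 11.94), against the direction of a lost male programme. The female-biased Cyp2a4 also lay lower in knockout mice 1, 2 and 4 (9.09 to 9.30) than in the wild-type arrays (9.76 to 10.72).

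As a hypothesis, the growth hormone dependent male programme may be lower in the knockout livers as a whole. The 25 list genes that did not pass lay lower in camera (p = 2.33e-06), but camera p was 0.0801 with an estimated correlation. The exact permutation p of their mean level, here not taken relative to all genes, was 0.171. Without knockout mouse 3, camera p was 0.000275, and 0.0591 with an estimated correlation. These genes therefore leave the hypothesis open. Growth hormone and body weight were not analysed here, and the labels gave no sex.

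Fibrosis and matrix genes (25 measured), hepatic stellate cell markers (13), neutrophil markers (13) and endothelial markers (15) had no member past the threshold, and none when adjusted over the list alone; their camera adjusted p were 0.98, 0.7, 0.495 and 0.118. Of 10 periportal and 14 pericentral hepatocyte genes 1, the pericentral Slc13a3, rose, and 2 periportal genes and 1 pericentral gene were higher when adjusted over the list alone, with camera adjusted p of 0.542 and 0.529.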
